A study of Rickenella mellea with 14 samples.

How the data were processed

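Polyadenylated RNA of the mushroom Rickenella mellea was sequenced from 14 samples, for which the labels name a TruSeq v2 library kit, a kit that does not mark the strand. Vegetative mycelium (n = 3) was grown on agar, while primordia (n = 3), young fruiting bodies (n = 3), and the caps (n = 3) and stipes (n = 2) of mature fruiting bodies were collected in the field. The mycelium libraries ran on 1 of the 2 flow cells and all field-collected libraries on the other, so stage, growth condition and flow cell cannot be told apart where mycelium is compared with any other group. The labels pool 1 stage 1 primordium library, replicate 2, with 2 stage 2 libraries. The series description calls the samples of a stage biological replicates without saying from how many individuals they came, so p-values measure the spread between these samples.

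Per the file headers, the authors gave each library a table of 17139 gene models of the set Ricmel1 with total and unique read counts, RPKM and TPM. The deposited read counts were whole numbers without normalization, and the column of expression values equalled the total counts in 100% of rows. The deposited RPKM values divided total reads by gene length and by the library total, and the deposited TPM values, not used in any test, summed to the same total in each library. Per the file headers a length in bases was given for each model, and 55.8% of the lengths were multiples of 3. A deposited matrix of log2 values covered 15477 genes. It held exactly the genes with at least 5 total reads in at least 4 libraries, and 100% of its values lay within 1e-06 of log2 RPKM recomputed here after TMM scaling. The submitters' processing notes name R 3.0.2, edgeR 3.4.2 and limma 3.18.13. The read mapper, its settings and the genome build are not given in the sources used here.

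The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on total read counts with TMM scaling. Genes passing the filterByExpr function of edgeR were tested, which left 15559 genes holding at least 99.61% of the reads of each library. All 14 libraries entered 1 fit, with 9 residual degrees of freedom, so that the 2 stipe libraries share the spread of the other groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with at least a 2-fold change. Levels of named genes are CPM after TMM scaling, given as mean ± SD. The thresholds of 1, 10 and 20 CPM used below were set on CPM by library total, without TMM. TMM factors were 0.572 to 0.786 in primordia and 1.14 to 1.35 in mycelium, so 1 threshold stands for different scaled levels there. Standard errors of log2 changes were computed as the change divided by the square root of the F statistic. Gene sets were tested with fry and camera of limma 3.58.1, camera with a preset inter-gene correlation of 0.01 and also with an estimated one. Fry asks whether the members change, and camera whether they change more than other genes.

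Library totals, in units of 1e6 reads, ran from 13.6 to 54.6, and 99.29% to 99.45% of reads were unique to 1 gene model. Detected genes were compared after random thinning of every library to the total of the smallest library. Counting floors take 3 reads as the upper limit for a count of 0, and intervals and floors cover counting error only. In simulated data for the step from mycelium to primordium, with 15358 genes, the test recovered 10% of genes changed 2-fold, 52% of those changed 4-fold, 88% of those changed 8-fold and 94% of those changed 16-fold, and 3.17% of calls were false. For the young fruiting body against the cap, with 15359 genes, 8%, 58%, 86% and 92% were recovered. For the young fruiting body against the stipe, with 15377 genes, the shares were 4%, 52%, 76% and 84%. Each simulation changed only 200 genes, fewer than were called in any of the real comparisons. The changed genes were drawn only from those above a minimum mean CPM, so recovery of low genes was not measured. The adjusted p depends on how many genes change, so these shares are not the sensitivity of the real comparisons.

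Choices were fixed before the data were examined, except those named as chosen later. Alternatives were DESeq2 1.42.0 size factors, library size without TMM, no low-count filter, DESeq2 and limma-voom as tests, unique reads, limma-trend on log2 RPKM with pseudocounts of 1 and 0.1, fits of only the groups compared, other fold thresholds, each library left out in turn, and the replicate number as a block. Removal of each library's trend on gene length was added after seeing the data, and was tested on simulated data, where a planted difference of 0.75 between long and short genes became 0.03. The trend removed also held each library's typical level, so this step changes the scaling as well.

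The named genes were, in each comparison, the 2 with the smallest adjusted p that rose and the 2 that fell. The files do not pair gene models with product names, so models are given by the number in their identifier, and no position on a chromosome is reported. For the same reason the 24 gene lists and 11 protein patterns fixed in advance were not analysed here.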

Results

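Read counts were obtained for 17139 gene models in 14 libraries covering 5 groups of Rickenella mellea, a small mushroom that grows among mosses. The groups followed development from vegetative mycelium through primordia and young fruiting bodies to the cap and the stipe of mature fruiting bodies. Stage 1 primordia were about 1 mm tall, stage 2 primordia 2 to 3 mm, young fruiting bodies 5 to 15 mm and mature fruiting bodies 20 to 32 mm. Library totals, in units of 1e6 reads, were 13.6 to 16.5 in mycelium, 14.3 to 18.4 in primordia, 32.9 to 44.6 in young fruiting bodies, 32.8 to 54.6 in caps and 21.5 to 35.3 in stipes. No reads were found for 697 gene models in any library, and 11906 had reads in every library.

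Libraries of the same group ranked genes alike, with a mean Spearman correlation across genes of 0.957 between caps, 0.954 between mycelia, 0.954 between young fruiting bodies, 0.924 between primordia and 0.977 between the 2 stipes. As a check for a library deposited more than once, no replicate pair agreed within counting noise (lowest chi-square per degree of freedom 51.4), which does not bear on whether the samples were independent. Mycelium replicates 2 and 3 correlated at 0.988, above replicate 1 with either of them, at 0.934 and 0.940. The stage 1 primordium library correlated at 0.923 and 0.916 with the stage 2 libraries, which correlated with each other at 0.932. Stipe libraries correlated more with primordia (mean 0.897) than cap libraries did (mean 0.848), a difference with an exact permutation p of 0.1, two-sided, the smallest that 10 splits allow.

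**Figure D1:**
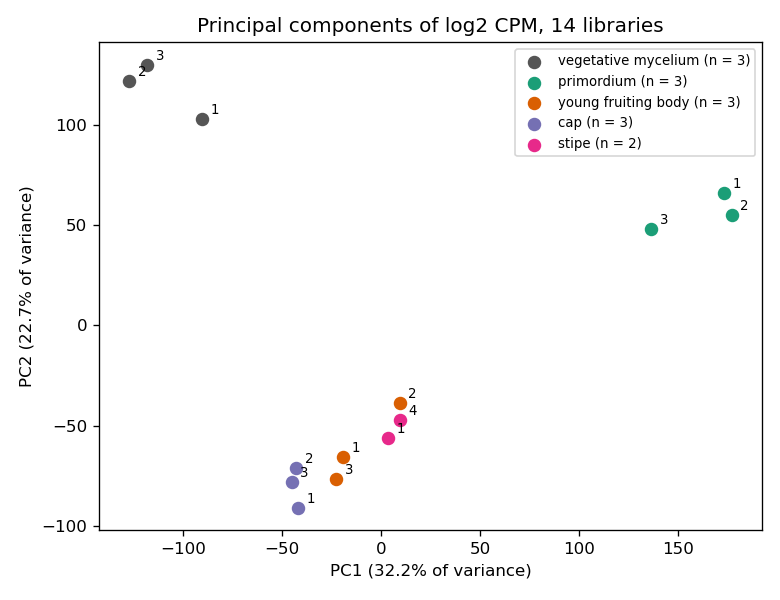
Principal components of log2 CPM for the 14 libraries, with PC1 (32.2% of variance) on the horizontal and PC2 (22.7%) on the vertical axis, 1 point per library, coloured by group and numbered by replicate. Mycelium and primordium libraries stand apart from each other and from the young fruiting bodies, caps and stipes.

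The first comparison asked which genes differ between vegetative mycelium and primordia. Gene model 822416 rose from 5.86 ± 1.34 to 764 ± 165 CPM (SD, n = 3 in each group), a log2 change of 7.03 ± 0.35 (SE; edgeR adjusted p = 5.71e-07). Gene model 851179 rose from 0.839 ± 0.071 to 67.3 ± 14.8 CPM, a log2 change of 6.32 ± 0.27 (edgeR adjusted p = 2.37e-07). Gene model 816303 fell from 566 ± 67.1 to 2.67 ± 0.29 CPM, a log2 change of -7.72 ± 0.39 (edgeR adjusted p = 5.71e-07). Gene model 763501 fell from 350 ± 105 to 3.39 ± 1.14 CPM, a log2 change of -6.69 ± 0.35 (edgeR adjusted p = 6.01e-07), with 81.53% of its reads unique. Of 15559 genes tested, 3135 rose and 3678 fell, and 494 rose and 957 fell at least 16-fold. Over all tested genes, called or not, 55.18% had no overlap between the libraries of the groups, where chance gives 10% for 3 against 3. At least 10 CPM in every mycelium library and no read in any primordium library was found for 10 genes, and the reverse for 2. Scaling by library size alone turned the split to 1642 risen and 6286 fallen genes and moved the median of all genes by -0.87 on the log2 scale. With the trend on gene length removed, chosen after seeing the data, 3546 rose and 3109 fell, and with only the mycelium and primordium libraries in the fit 2664 rose and 2630 fell, so which direction held more genes depended on the processing. Among genes ranked by length and cut into 3 equal bins, the longest bin had a median log2 change 0.77 above that of the shortest.

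From primordium to young fruiting body, gene model 483798 rose from 6.59 ± 1.54 to 218 ± 22.2 CPM (SD, n = 3 in each group), a log2 change of 5.04 ± 0.38 (SE; edgeR adjusted p = 3.34e-05). Gene model 712798 rose from 9.23 ± 1.29 to 83.0 ± 14.1 CPM, a log2 change of 3.17 ± 0.22 (edgeR adjusted p = 3.34e-05). Gene model 808082 fell from 1590 ± 328 to 56.6 ± 12.1 CPM, a log2 change of -4.81 ± 0.32 (edgeR adjusted p = 3.34e-05). Gene model 826281 fell from 1150 ± 196 to 107 ± 21.9 CPM, a log2 change of -3.43 ± 0.27 (edgeR adjusted p = 3.34e-05). In total 3192 genes rose and 2045 fell. Over all tested genes 46.55% had no overlap between the groups' libraries, against 10% by chance. With library size alone the split was 4880 risen and 1100 fallen, and the median of all genes moved by 0.54. With the trend on gene length removed it was 2438 risen and 2737 fallen. That removal also re-scales each library, so the turn cannot be put down to length alone. With DESeq2 size factors, another scaling, the split was 2835 risen and 2376 fallen. The bin of longest genes had a median log2 change of -0.54 relative to the shortest.

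Many genes moved in opposite directions at these steps. Of the genes called at both, 1992 fell and then rose and 1433 rose and then fell, while 82 rose at both and 66 fell at both. Independent lists of these sizes would share 754.6, 412, 643.2 and 483.4 genes, and 20 simulations of unchanged groups shared 0 genes in each class, a value that leaves out any real effect. Both comparisons use the primordium libraries, so part of the excess in opposite directions may come from them. In an alternative chosen after seeing the data, 1 primordium library served 1 step and the other 2 the other step, in all 6 ways. Then 1316 to 1640 genes fell and rose, 837 to 1185 rose and fell, 95 to 125 rose at both and 81 to 123 fell at both, where independent lists would share 578.6 to 688.6, 273.3 to 360.8, 481.1 to 591.8 and 328.7 to 422.7. The lone library was assumed to vary like the other groups. A bias common to all primordium libraries would stay in every such split. The longest genes moved by 0.77 relative to the shortest into primordium and by -0.54 out of it. The overlap was not recomputed with the trend on gene length removed or with another scaling.

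**Figure D2:**
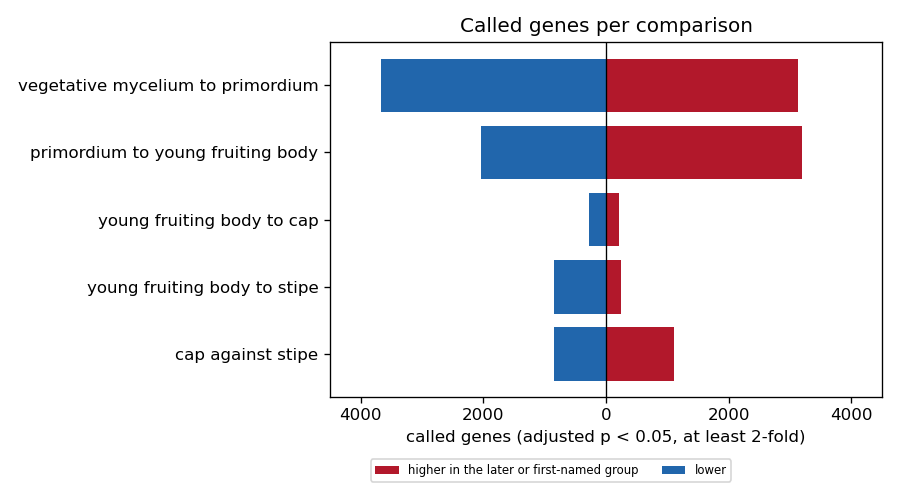
Called genes in each of the 5 comparisons, with bars to the right for genes higher in the later or first-named group and to the left for genes lower there, on a linear axis of gene numbers. The step from mycelium to primordium has 6813 called genes and the step from young fruiting body to cap has 485.

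Between young fruiting body and cap, gene model 833531 rose from 8.86 ± 1.22 to 232 ± 106 CPM (SD, n = 3 in each group), a log2 change of 4.71 ± 0.39 (SE; edgeR adjusted p = 0.000269). Gene model 811097 rose from 17.2 ± 2.42 to 151 ± 9.44 CPM, a log2 change of 3.13 ± 0.27 (edgeR adjusted p = 0.000269). Gene model 794115 fell from 297 ± 31.9 to 11.1 ± 3.00 CPM, a log2 change of -4.75 ± 0.31 (edgeR adjusted p = 3.74e-05), with 88.14% of its reads unique. Gene model 791051 fell from 168 ± 41.5 to 12 ± 3.57 CPM, a log2 change of -3.81 ± 0.37 (edgeR adjusted p = 0.000437). In total 209 genes rose and 276 fell. Caps and stipes are parts of mature fruiting bodies, while the young fruiting body group is not divided into such parts. A difference between parts and a change with stage therefore cannot be told apart here. Over all tested genes 29.38% had no overlap between the groups' libraries, against 10% by chance. With library size alone the split was 301 and 119, with a median shift of 0.33. The count of 485 dropped to 149 without cap replicate 2 (97 risen, 52 fallen), 189 without cap replicate 1 (113 risen, 76 fallen), 207 without young fruiting body replicate 1 and 225 without young fruiting body replicate 2.

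Between young fruiting body and stipe, gene model 822416, which also rose from mycelium to primordium, rose from 634 ± 139 (SD, n = 3) to 3230 ± 93.4 CPM (n = 2), a log2 change of 2.35 ± 0.30 (SE; edgeR adjusted p = 0.00636). Gene model 837327 rose from 74.9 ± 6.80 to 220 ± 9.43 CPM, a log2 change of 1.56 ± 0.20 (edgeR adjusted p = 0.00636). Gene model 834744 fell from 95.8 ± 12.8 to 27.7 ± 6.61 CPM, a log2 change of -1.79 ± 0.22 (edgeR adjusted p = 0.00636). Gene model 720102 fell from 305 ± 48.0 to 61.2 ± 1.94 CPM, a log2 change of -2.32 ± 0.28 (edgeR adjusted p = 0.00636), but only 21.01% of its reads were unique, so its level is uncertain. In total 251 genes rose and 853 fell. As for the cap, part and stage cannot be told apart in this comparison. Over all tested genes 49.5% had no overlap between the groups' libraries, against 20% by chance for 3 against 2. With library size alone 268 rose and 521 fell, with a median shift of 0.14. Without stipe replicate 4, edgeR called 0 genes (1819 at an unadjusted p under 0.05), limma-voom 198 and DESeq2 627. The count was 358 without stipe replicate 1 (93 risen, 265 fallen) and 333 without young fruiting body replicate 1 (27 risen, 306 fallen).

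Cap and stipe differed in 1954 genes, of which 1113 were higher in cap and 841 higher in stipe. Gene model 811097 was higher in cap at 151 ± 9.44 CPM (SD, n = 3) than in stipe at 7.05 ± 1.92 CPM (n = 2), a log2 difference of 4.42 ± 0.34 (SE; edgeR adjusted p = 7.42e-05). Gene model 150660 was higher in cap at 173 ± 36.4 than in stipe at 10.4 ± 2.03 CPM, a log2 difference of 4.05 ± 0.33 (edgeR adjusted p = 9.97e-05). Gene model 794115 was lower in cap at 11.1 ± 3.00 than in stipe at 431 ± 71.4 CPM, a log2 difference of -5.28 ± 0.33 (edgeR adjusted p = 2e-05). Gene model 837327 was lower in cap at 27.0 ± 3.05 than in stipe at 220 ± 9.43 CPM, a log2 difference of -3.02 ± 0.20 (edgeR adjusted p = 2.73e-05). Over all tested genes 55.12% had no overlap between the groups' libraries, against 20% by chance for 3 against 2. With library size alone 1330 were higher in cap and 578 in stipe, with a median shift of 0.20. The count was 278 without stipe replicate 4, with 76 higher in cap and 202 higher in stipe, 847 without stipe replicate 1 and 1293 without cap replicate 3.

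**Figure D3:**
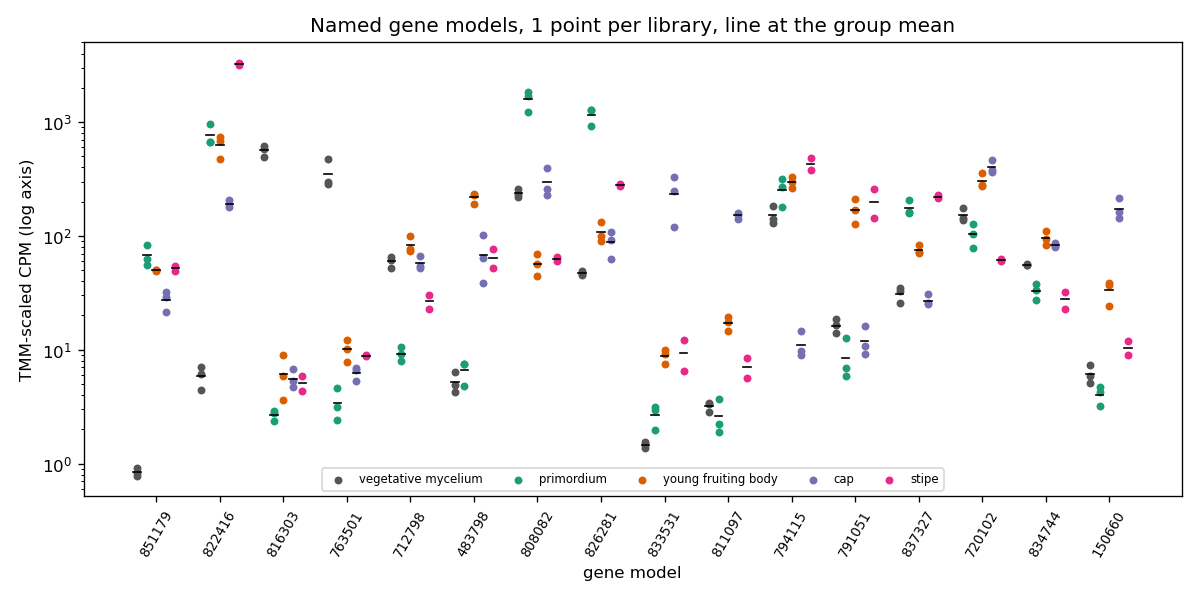
Levels of the 16 named gene models in TMM-scaled CPM on a log axis, 1 point per library, coloured by group, with a line at each group mean. Gene model 822416 lies at 5.86 CPM in mycelium and at 3230 CPM in stipe, and gene model 794115 lies at 11.1 CPM in cap.

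Among the 4 field-collected groups, which share a flow cell, 6844 genes (43.99% of those tested) changed. Their highest mean was in primordium for 2426 genes, in cap for 1755, in young fruiting body for 1503 and in stipe for 1160. Their lowest mean was in primordium for 3166 genes. With library size alone these primordium counts became 1087 and 5779.

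The genes that separated cap from stipe were followed in libraries outside that comparison. Of the 1113 genes higher in cap, 721 rose and 48 fell from primordium to young fruiting body, where independent lists would give 228.3 and 146.3. Of the 841 genes higher in stipe, 104 rose and 269 fell at that step, where 172.5 and 110.5 would be given. From mycelium to primordium, 442 of the genes higher in stipe rose and 98 fell, where independent lists would give 169.5 and 198.8. Of the genes higher in cap, 93 rose and 496 fell at that step, where 224.3 and 263.1 would be given. That step also changes growth condition and flow cell. With library size alone, an alternative chosen after seeing the data, the median log2 change of the genes higher in stipe went from -0.58 to -0.035 at the step to the young fruiting body and from 1.29 to 0.41 at the step to the primordium, and that of the genes higher in cap from 1.57 to 2.12 and from -0.90 to -1.75. At the step to the young fruiting body, the fry test gave adjusted p-values of 3.24e-05 for the cap genes and 0.00129 for the stipe genes. At the step to the primordium it gave 0.00129 for the cap genes and 9.6e-06 for the stipe genes. By camera with the preset correlation all 4 passed. With an estimated correlation the camera adjusted p at the step to the young fruiting body was 0.0768 for the cap genes and 0.0804 for the stipe genes. At the step to the primordium it was 0.216 for the cap genes and 0.0764 for the stipe genes, so no set passed.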

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

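The tests of depth, of recurrence among field libraries and of left-out libraries for the genes of opposite direction in this part were chosen after the result was seen. Signal was found in gene models left out of the comparisons. In the stage 1 primordium library, replicate 2, 21 untested gene models stood at 10 CPM or more while every other library stayed under 1 CPM. Of these, 18 had no read in any other library, and the highest had 18091 reads. The same held for 5 gene models in primordium replicate 3, 2 in young fruiting body replicate 1 and 1 in mycelium replicate 1. Separately, 23 genes were called in opposite directions in cap and in stipe relative to the young fruiting body. For each the direct test of cap against stipe was passed, which opposite calls in the same fit nearly ensure, so it adds little. Of these 23 genes, 7 were higher in cap and 16 higher in stipe, where independent lists would share 11.46 and 4.452. In the same direction, 30 genes fell in both tissues and 4 rose in both, where independent lists would share 15.13 and 3.372. In 20 simulations of unchanged groups 0 genes were shared in each class, a value that leaves out any real effect. All these lists use the young fruiting body libraries. That group is not divided into cap and stipe, so opposite calls cannot tell a difference between parts from a change with stage. Without stipe replicate 4 the number was 0, without stipe replicate 1 or young fruiting body replicate 1 it was 8, without cap replicate 2 it was 12, without young fruiting body replicate 3 it was 13 and without cap replicate 3 it was 15.

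Libraries of the same group also differed in which genes had any reads. At 1 common depth, 57 genes had no read in 1 of mycelium replicates 1 and 2 and at least 20 CPM in the other, against 0 between replicates 2 and 3. With that 0 set at the floor of 3, the ratio was at least 19, which decides nothing about depth, since 20 CPM is 271 reads at this depth and the definition itself leaves out genes lost by counting. Over the 186 such genes of all groups the median share of unique reads was 100%, which argues against reads shared between near-identical copies. Of the 66 such genes in mycelium, 28.8% were also on in some and off in other field libraries, above the highest of 1000 random sets matched on expression (9.09%), but those libraries span several stages, so this does not separate individuals from stage. Between field libraries of the same stage the share was 15.2%, against at most 4.55% in the random sets, so individuals that differ in the genes they carry or express are a candidate explanation, while genes that vary with local conditions stay open and the labels give 1 strain for all libraries.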

How the results depend on the processing

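The removal of the gene length trend, and the tests on groups of highest level and on cap and stipe genes, were chosen after the result was seen. Of 114 alternative counts of called genes, 92 stayed within 1.5 times the main count, and of 364 alternative values of named genes, 354 kept direction and call and the others kept direction. Requiring 4-fold left 3991 genes from mycelium to primordium, 2603 from primordium to young fruiting body, 235 to cap, 284 to stipe, 802 between cap and stipe and 3819 in the 4-group test, fewer by construction. From young fruiting body to cap (485), DESeq2 called 1135, limma-voom 993 and limma-trend on log2(RPKM + 1) 862, and to stipe (1104) DESeq2 called 1881; the cause was not tested. Removing the length trend gave 6655, of which 5802 were also called in the main test, from mycelium to primordium and 5175, of which 4416, from primordium to young fruiting body. Library similarity was 0.95, and 0.938 on log2 RPKM and 0.951 on unique reads.

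With each library left out, counts ran from 5938 to 7105 for mycelium to primordium, 4289 to 5666 for primordium to young fruiting body, 149 to 424 to cap, 0 to 1176 to stipe, 278 to 1617 between cap and stipe, and 5715 to 7176 in the 4-group test. Where 1 stipe library was left, it was assumed to vary like the other groups.

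Same-numbered libraries did not deviate together (correlations from -0.13 to 0.038 over 9 pairs), so the numbers gave no sign of pairing at the steps checked. Those were mycelium to primordium, primordium to young fruiting body and young fruiting body to cap. Comparisons with stipe were not checked. Cap 1 and stipe 1 had the highest Spearman correlation of any cap and stipe pair (0.931, against 0.918 for cap 1 and stipe 4). Stipe 1 was also closer than stipe 4 to cap 2 (0.9082 against 0.8908) and to cap 3 (0.9142 against 0.8965). Cap 1 was the closest cap to both stipes, so that correlation is no sign of pairing. Pairing of caps with stipes was not tested and stays open. With the replicate block, on the libraries of the groups compared, 4584 genes were called from mycelium to primordium, 2770 from primordium to young fruiting body and 0 to cap (edgeR; 2398 at an unadjusted p under 0.05, limma-voom 169, DESeq2 1439). The cap and stipe comparisons with stipe share only 1 number and had no such fit. The tests of the 24 gene lists fixed in advance were not run. In simulated data with only 200 genes changed, none of them low in mean CPM, 4% to 10% of genes changed 2-fold were recovered. The share was the same with or without the fold threshold. These shares do not measure recovery in the real comparisons, where more genes were called.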

Other observations

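The tests of thinned detection and of field growth or flow cell in this part were chosen after the result was seen. Stipe libraries ranked closer to primordium libraries than cap libraries did. Thinned to 1 depth the gap kept 99.9% of its size, and over the 9418 genes with a mean of at least 10 CPM it was 335% of its size, which argues against depth and against noise of low genes. Genes higher in stipe than in cap had a median log2 change of -0.576 from primordium to young fruiting body, and genes higher in cap 1.57, each past the fry test. A hypothesis is that primordia may be made up mostly of stipe-like tissue. However, the median of the stipe genes was -0.0348 with library size alone, and neither set passed camera with an estimated correlation. Young fruiting bodies correlated alike with caps (mean 0.936) and with stipes (mean 0.935). The medians therefore partly restate the closeness of stipes to primordia and are no separate test of this hypothesis.

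Primordium libraries detected fewer genes than mycelium libraries, with 13658 ± 213 against 14996 ± 103 at 1 depth (SD, n = 3 in each group; exact permutation p = 0.1, the smallest possible). The lowest mycelium library lay 1015 genes above the highest primordium library after thinning, which argues against depth. With the reads of the 100 most abundant genes left out it lay 1006 above, which argues against those 100 genes as the cause. However, 50% of the reads were held by 273 to 467 genes in primordia and by 759 to 912 in mycelium. Reads taken up by a wider set of abundant genes therefore stay open. Long genes rose relative to short ones by 0.768 ± 0.049 (SE from a bootstrap over genes) on the log2 scale. That SE leaves out the spread between libraries. A length bias could contribute, although this test measured levels and not detection. Every young fruiting body, cap and stipe library, also field-collected and on the primordium flow cell, detected at least 1105 more genes than the highest primordium library, which argues against field growth or flow cell as the cause.

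With 10 splits of the 6 libraries of each comparison, the share of splits with as many called genes as the real one cannot fall under 0.05. Each split was fitted like the main test, with all 14 libraries and only the labels of those 6 changed. The real split alone, 1 of 10, reached 6813 genes from mycelium to primordium, 5237 from primordium to young fruiting body and 485 from young fruiting body to cap, and the highest other split called 1 gene in each. Every other split mixes libraries of the compared groups, which raises the spread within groups. Few calls are therefore built into those splits, and they give no baseline for chance.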
